A study of Homo sapiens with 36 samples.

How the data were processed

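The study hybridised RNA of 9 human liver tumour cell lines to 2-colour arrays, with 4 arrays for each line and 36 arrays in all. Per the labels, each array carried total RNA of 1 line in the Cy5 channel and a sample called universal control in the Cy3 channel. Per the labels, RNA was extracted with a Qiagen RNeasy kit and marked with a Genisphere 3DNA kit, and the image program came from Axon Instruments. No array had the dyes exchanged, so a dye effect of a probe could not be separated from a difference between a line and the control. It cancels when lines are compared with each other, provided it was the same on all arrays.

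The deposited table gives a single value per probe and array, and its values were taken as log2 ratios of the cell line over the universal control. The log base, the direction, the background correction and the normalization are not given in the deposited labels. Direction was taken from the dyes and titles. Base 2 was taken from the range, because the highest deposited value, 12.69, exceeds 11.1 and 4.82, the natural and base 10 logs of the 16-bit maximum. This holds only if no signal fell below 1, which an unknown background correction could allow, so the base, and with it every fold, stays an assumption. The deposited array medians ran from -0.01 to 0.01, so each array had been brought near a median of 0 by a method the labels leave out. The median absolute deviation of an array went in steps by sets of lines. It was 0.283 to 0.287 in HepG2 and Hep3B, and 0.315 to 0.317 in PLC/PRF/5, SNU-182 and SNU-354. In SNU-368, SNU-387, SNU-449 and SNU-475 it was 0.331 to 0.334. Scaling or handling that differed between these sets cannot be told apart from the lines. The means of single probes ran from -2.52 to 3.38, so probes had not been centred. Intensities and spot quality were not used here, so signal over background is unknown for every value, and the precision is limited by the number of arrays.

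The table held 24288 probes and 3839 missing values, 0.439% of all values. A probe was kept if at least 2 of the 4 arrays of every line had a value, which left 24035 probes and removed 253. Each array was centred on its median over these probes. In the array annotation 18597 probes had 1 gene symbol, 70 had several and 5621 had none. Of the first group, 18563 matched a human RefSeq gene by gene ID and 34 did not, and 0 of the matched symbols differed. Probes with 1 symbol were averaged per gene, which gave 8799 genes, of which 4408 had several probes and 8756 had a value on all 36 arrays. Probes without a single symbol were left out of the comparisons except in the alternative run per probe.

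All comparisons used limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading and matplotlib 3.10.9 in Python 3.11.15 for the plots. A linear model with 9 line means was fitted to the 36 arrays, with moderated variances and Benjamini-Hochberg adjusted p. Differences among the lines were tested with the moderated F-test. Each line was compared with the mean of the 8 other line means, with 0 (the control level), and with each other line in 36 pairs. The SE of a line against the other 8 comes from the moderated variance pooled over all 36 arrays. It does not measure the spread of the 4 arrays of that line alone, and the n beside it gives the arrays of the line. For the mean of the 9 lines against the control, and for the 6 lines whose names begin with SNU against the 3 others, the 4 arrays were first averaged and the line was the replicate. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1, which is 2-fold. For the F-test the range of the 9 line means had to reach 1. The labels do not say whether the 4 arrays of a line came from 1 culture or several, so the tests over arrays measure only the spread between arrays. The universal control has no arrays of its own, so its spread is left out of every test against it. Arrays of different lines with the same replicate number, 5 to 8, were not paired, because their deviations from the line means had a median Pearson correlation of 0.000944.

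Before the data were examined, 35 gene lists with 697 genes were fixed, of which 478 genes were measured. Lists with at least 5 measured genes, 32 in all, were tested with camera at a preset correlation of 0.01 between genes. This was done for each line against the other 8 and for the SNU comparison, 320 tests adjusted together. Camera with an estimated correlation, camera on ranks and fry were run beside it. For list members, calls were also counted with p adjusted over the list alone.

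The genes to be named were also chosen by a rule fixed before the data were examined. They are the 10 genes with the largest SD of the line means, and the 3 highest and 3 lowest called genes of each line whose arrays all lay on that side of the other lines' mean. For the mean of the 9 lines, they are the 10 highest and 10 lowest called genes with the same sign in all lines. For the SNU comparison, where too few passed, they are the 5 with the smallest p in each direction. Members of the fixed lists with the largest differences serve as examples, and ALB, VIM and CDH1 were followed throughout. AFP, GPC3 and HNF4A were on the same fixed list but had no named probe. Placeholder symbols, XIST and Y-linked genes were skipped.

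The procedure was tested on simulated data of 8799 genes with 100 genes changed by 1.5 and 100 changed by 3 on the log2 scale. The changed genes were drawn at random and the noise was independent between genes, so the recovery is an average over all genes. Calls in 1 line against the other 8 recovered 100% and 100% of them with 0 false calls. For these calls and the F-test only 1 line was changed, so a mean of the other 8 shifted by several lines was not simulated. For the F-test the recovery was 99% and 100%, for the mean of the 9 lines 99% and 99%, and for the SNU comparison 89% and 99% with 1 false call. In the list test the raised list was called, and 0 of 30 lists without its genes were.

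Alternatives were no centring, quantile normalization, scaling of arrays to 1 median absolute deviation, stricter and looser filters on missing values, a filter at an absolute log ratio of 0.5, and no averaging of probes. Others were no fold limit, an adjusted p under 0.01, a trended and robust variance, a replicate block, and fits without each replicate or line. The line as a random block, and the spread between lines as the error for single lines, were run as well. For the last of these, the mean of the line was set against the 8 line means, whereas the plan had named its 4 arrays. A fit without the Hep3B and SNU-182 arrays was added after the data had been seen.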

Results

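Transcript levels were measured in 9 human liver tumour cell lines against a common universal control RNA, on 2-colour arrays. The lines were HepG2, Hep3B, PLC/PRF/5, SNU-182, SNU-354, SNU-368, SNU-387, SNU-449 and SNU-475, with 4 arrays each and replicate numbers 5 to 8. Each value was taken as a log2 ratio of the line over the control, and 8799 genes were compared. The SD of the deposited values on an array ran from 0.405 to 0.621, and an array lacked between 0 and 230 values. Arrays of the same line had a Pearson correlation across genes of 0.623 to 0.889, median 0.795, and arrays of different lines of 0.0898 to 0.729, median 0.276. Genes are not independent replicates, so these correlations describe similarity and carry no test.

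The title of the series names the comparison of hepatoma lines with the control, and the first question was which transcripts differed among the lines. Genes of proteins that the liver secretes into plasma differed most. APOA2, a protein of high-density lipoprotein, ran from a mean of 6.36 (SD 0.46, n = 4) in HepG2 to -0.51 (SD 1.14, n = 4) in SNU-449. RBP4, the plasma carrier of retinol, ran from 6.31 (SD 0.24) in HepG2 to -0.49 (SD 0.36) in SNU-368. AGT, the precursor of angiotensin, was highest in PLC/PRF/5 at 6.09 (SD 0.36) and lowest in SNU-354 at -0.19 (SD 0.10). Means were highest in HepG2 also for AHSG (6.22), LCAT (6.01), APOC2 (5.51), APOH (5.46), TF (5.12) and A2M (4.90), all of which encode plasma proteins. Of the 10 genes with the largest SD of line means, PTK2 was the 1 annotated to a gene, focal adhesion kinase, that encodes no plasma protein. This single probe had means of 5.86 in HepG2, 5.17 in PLC/PRF/5 and 4.24 in SNU-182, the lines high in plasma proteins, and -0.12 in SNU-368. Its annotation was not checked against its sequence, so the name is uncertain here and in the comparisons that follow.

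By the limma moderated F-test, 1924 of 8799 genes differed at an adjusted p under 0.05 with a range of line means of at least 1, and 7416 passed on the adjusted p alone. The adjusted p of APOA2 was 4.39e-21. Between pairs of lines the number of called genes ran from 83 to 574, with a median of 350.5 over 36 pairs. HepG2 and SNU-182 lay closest, with 83 called genes and a Pearson correlation of line means across genes of 0.807. The most genes separated HepG2 from SNU-387.

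**Figure D1:**
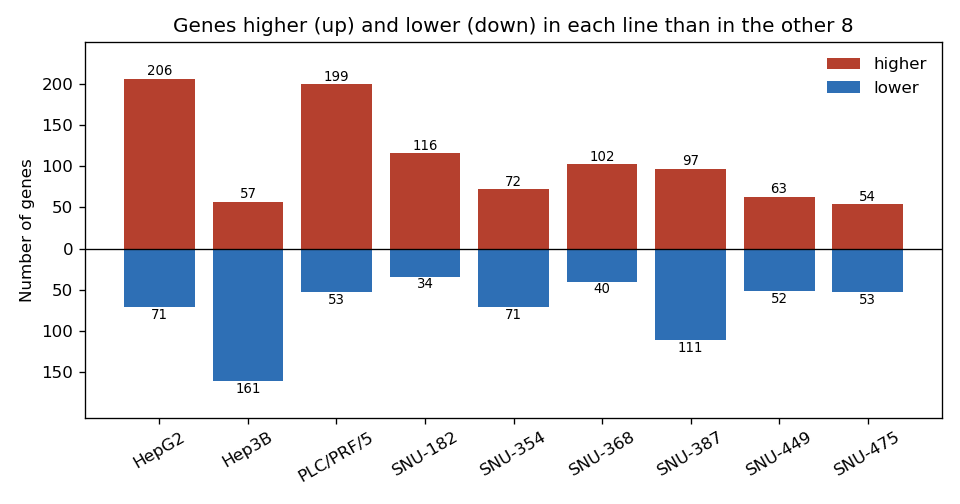
Number of genes called higher (red, above 0) and lower (blue, below 0) in each cell line than in the mean of the other 8 lines, from 4 arrays per line and 8799 genes. HepG2, PLC/PRF/5, SNU-182 and SNU-368 had mostly higher genes, and Hep3B had 57 higher and 161 lower, a balance that turned to 133 and 114 after quantile normalization.

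Each line was then compared with the mean of the other 8 lines, which asks what set it apart, and the gene lists fixed before the data were examined describe the groups. For plasma protein genes HepG2, SNU-182 and PLC/PRF/5 raised that mean for the other lines, which fell under it while near the control level. Of 358 pairs of a named gene and a line that passed, all values of the line lay on the stated side in 357, and FABP1 in SNU-354 was the exception with 3 of 4 arrays. The naming rule required this of the 3 highest and 3 lowest genes of each line. A call also needs a difference of at least 1, so the count is largely fixed in advance. In 350 counts of list members, from each line against the other 8 and the 6 SNU lines against the 3 others, 0 changed when p was adjusted over the list alone. Of 320 list tests 98 were called with the preset correlation, 54 with an estimated one and 76 on ranks. For the plasma proteins the estimated correlation was 0.106, above the preset 0.01. With it the camera adjusted p of that list was 0.000156 in HepG2, against 1.02e-29 with the preset one. The tests over arrays take the spread between arrays within lines, pooled over all 9 lines, as the error. With the spread between lines as the error, the called genes were 0 in HepG2 (277 before), 2 in Hep3B (218), 22 in PLC/PRF/5 (252), 1 in SNU-182 (150), 11 in SNU-354 (143), 8 in SNU-368 (142), 30 in SNU-387 (208), 9 in SNU-449 (115) and 0 in SNU-475 (107). At an unadjusted p under 0.05 in limma over arrays, HepG2 had 4331 genes and SNU-475 had 4409.

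**Figure D2:**
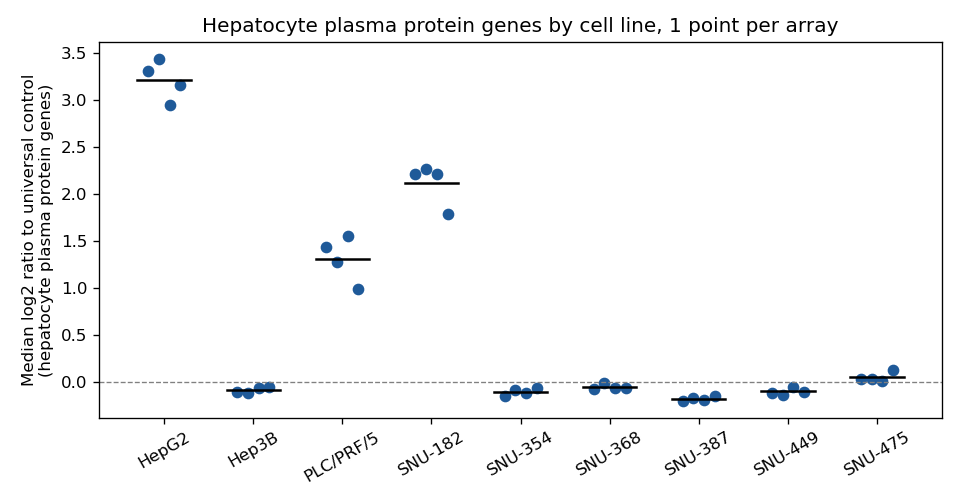
Median log2 ratio to the universal control over 32 hepatocyte plasma protein genes, with 1 point per array and a black line at the mean of the 4 arrays of each cell line. HepG2, SNU-182 and PLC/PRF/5 lie above 0, and the other lines lie near 0.

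In HepG2 the transcripts of secreted liver proteins were higher than in the other lines. AHSG, a plasma glycoprotein, was higher by 5.92 ± 0.12 on the log2 scale (SE, n = 4 arrays, limma adjusted p = 5.77e-27). RBP4 was higher by 5.37 ± 0.17, LCAT, which esterifies cholesterol in plasma, by 5.24 ± 0.12, and ALB, serum albumin, by 3.57 ± 0.08, although the ALB probes ranged from 1.32 to 5.44. Of 32 hepatocyte plasma protein genes 26 were higher and 0 lower, with a median of 2.87 (camera adjusted p = 1.02e-29). Acute phase proteins followed with 8 of 12 higher (adjusted p = 6.99e-08), among them ORM1 (4.11 ± 0.17) and HP (3.19 ± 0.11). Fatty acid and triglyceride synthesis had 5 of 13 higher (adjusted p = 0.00624), including FABP1, a fatty acid carrier (3.45 ± 0.25), and PLIN2, which coats lipid droplets (2.01 ± 0.09). On ranks this list missed the threshold (camera adjusted p = 0.117). All 3 measured metallothioneins, which bind metals, were higher, led by MT1E (2.63 ± 0.08), and a list of 3 was too short to test. On the lower side stood LDHB, a lactate dehydrogenase subunit (-2.69 ± 0.10), S100A6, a calcium-binding protein (-2.57 ± 0.06), and HSPB1, a small heat shock protein (-2.41 ± 0.07). Of 21 mesenchymal genes 4 were lower and 1 higher (adjusted p = 0.00131), with VIM, vimentin, at -1.50 ± 0.05 and its probes from -2.73 to -0.07. In all 277 genes were called, 206 higher and 71 lower, and 170 after quantile normalization.

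In the arrays labelled Hep3B, plasma protein transcripts were lower than in the mean of the other lines, and cathepsin L was higher. CTSL, a lysosomal protease, was higher by 2.70 ± 0.07 (SE, n = 4 arrays, limma adjusted p = 7.24e-25), CRIP2 by 2.20 ± 0.08 and PSMG3, a proteasome assembly factor, by 2.13 ± 0.07. The lowest were the aldo-keto reductases AKR1C4 (-3.58 ± 0.13), AKR1C3 (-3.44 ± 0.16) and AKR1C2 (-3.42 ± 0.14), which are close paralogs. Of 13 NRF2 targets, which include such enzymes, 3 were lower and 0 higher (camera adjusted p = 0.00372, and 0.0525 with camera on ranks). Of 32 plasma protein genes 17 were lower and 0 higher, with a median of -1.08 (adjusted p = 1.28e-10), among them F2, prothrombin (-2.36 ± 0.12), and ALB (-1.49 ± 0.08). Cholesterol synthesis had 2 of 13 lower (adjusted p = 0.000117), IDI1 (-1.22 ± 0.05) and FDPS (-1.11 ± 0.04, and -0.96 after quantile normalization). Fatty acid synthesis had 3 of 13 lower (adjusted p = 0.0171), led by SCD, the stearoyl-CoA desaturase (-1.76 ± 0.04). On ranks the fatty acid list missed the threshold (camera adjusted p = 0.109). MYBL2, a transcription factor of dividing cells, stood at -3.41 ± 0.05, and it was the only 1 of 29 cell cycle genes to pass; that list had an adjusted p of 0.0108, and an adjusted p = 0.0716 with an estimated correlation. DLK1, a fetal liver marker, was at -3.27 ± 0.06. Called were 57 genes higher and 161 lower, which became 133 and 114 after quantile normalization.

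PLC/PRF/5 combined high fibrinogen with high cancer-testis antigens and low metallothioneins. S100A9, a calcium-binding protein of myeloid cells, was higher by 5.02 ± 0.22 (SE, n = 4 arrays, limma adjusted p = 1.01e-18) and AGT by 4.29 ± 0.15. MAGEA2, of a family normally made in testis, was higher by 4.06 ± 0.23, and 5 of 6 cancer-testis antigens were higher (camera adjusted p = 5.96e-05), and the MAGEA genes are close paralogs. Plasma proteins had 16 of 32 higher and 1 lower (camera adjusted p = 1.64e-06, and 0.0393 with an estimated correlation). The higher ones included the iron carrier TF (3.66 ± 0.14) and the fibrinogen chains FGG (3.33 ± 0.08) and FGA (3.13 ± 0.12). Of 15 unfolded protein response genes 3 were higher (adjusted p = 1.56e-05), led by the chaperone PDIA4 (1.86 ± 0.06). The chemokine CCL20 was higher by 3.47 ± 0.11 and the protease inhibitor SPINT2 by 2.98 ± 0.11. The lowest were S100A6 (-4.18 ± 0.06), MT1E (-3.91 ± 0.08) and S100A1 (-3.85 ± 0.09), and all 3 metallothioneins were lower, with MT2A at -3.09 ± 0.06 and MT1X at -2.46 ± 0.07. Collagens and matrix genes had 2 of 21 lower (adjusted p = 0.000415), and SPP1, osteopontin, was at -2.15 ± 0.11. In all 252 genes were called, 199 higher and 53 lower.

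The arrays labelled SNU-182 were high in plasma protein and acute phase transcripts. APOA2 was higher by 4.04 ± 0.22 (SE, n = 4 arrays, limma adjusted p = 1.13e-15), LCAT by 3.70 ± 0.12, AHSG by 3.51 ± 0.12 and ALB by 2.68 ± 0.08. Of 32 plasma protein genes 20 were higher and 0 lower, with a median of 1.45 (camera adjusted p = 1.05e-25). Acute phase proteins had 7 of 12 higher (adjusted p = 1.63e-09), including ORM1 (3.02 ± 0.17) and HAMP, the iron hormone hepcidin (2.96 ± 0.31). Oncofetal and progenitor markers had 3 of 9 higher (adjusted p = 1.89e-05), with PEG10, an imprinted gene, at 2.29 ± 0.10. Amino acid catabolism had 2 of 13 higher (adjusted p = 0.000234), HPD (1.91 ± 0.16) and AGXT (1.51 ± 0.07), enzymes of tyrosine and glyoxylate breakdown. HPD lay below the control in all 9 lines, so in SNU-182 it was only less low than in the mean of the others. ANXA1, a phospholipid-binding protein, was lowest at -2.14 ± 0.06, followed by LDHB at -1.90 ± 0.10 and OCIAD2 at -1.62 ± 0.16. Mesenchymal genes had 3 of 21 lower (adjusted p = 8.94e-05), among them TPM2 (-1.30 ± 0.07) and MSN (-1.26 ± 0.06). In all 150 genes were called, 116 higher and 34 lower.

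SNU-354 was high in epithelial junction transcripts and low in plasma protein transcripts. The creatine kinases CKMT1B (2.76 ± 0.13, SE, n = 4 arrays, limma adjusted p = 1.23e-17) and CKB (2.72 ± 0.08) and SH3YL1 (2.56 ± 0.09) were highest. Of 18 epithelial junction genes 5 were higher and 0 lower, with a median of 0.68 (camera adjusted p = 5.53e-12), including EPCAM, an adhesion molecule (1.83 ± 0.08), and CLDN7, a tight junction protein (1.71 ± 0.08). KRT19, a duct cell keratin, was higher by 2.13 ± 0.09, and HADHB, a subunit of the fatty acid oxidation complex, by 2.46 ± 0.05. Cholesterol synthesis moved up as a list with a median of 0.48 (adjusted p = 5.01e-06), although 0 of 13 members passed. The lowest were AKR1C2 (-2.96 ± 0.14), SPP1 (-2.87 ± 0.11) and a single probe annotated to PM20D2 (-2.77 ± 0.12). Among other lower genes were FN1, fibronectin (-2.23 ± 0.07), and PEG10 (-2.16 ± 0.10). The PM20D2 probe was low in SNU-354 and Hep3B, where AKR1C2 was low too, and its annotation was not checked against its sequence. Of 32 plasma protein genes 15 were lower and 0 higher (adjusted p = 1.22e-16), among them TF (-1.97 ± 0.14). NRF2 targets had 3 of 13 lower (adjusted p = 4.73e-05), and these were AKR1C members. Mesenchymal genes had 2 of 21 lower (adjusted p = 2.74e-06). In all 143 genes were called, 72 higher and 71 lower.

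In SNU-368 duct cell markers and NRF2 targets were higher than in the mean of the other 8 lines. MMP7, a matrix protease, was higher by 3.26 ± 0.29 (SE, n = 4 arrays, limma adjusted p = 9.83e-11), UBD, a ubiquitin-like protein, by 2.72 ± 0.08, and NRCAM, a neuronal adhesion molecule, by 2.71 ± 0.13. Of 8 cholangiocyte markers 3 were higher (camera adjusted p = 0.00347), SPP1 (2.19 ± 0.11), ANXA4 (1.11 ± 0.11) and KRT7 (1.07 ± 0.05), and without SNU-387 the last pair stood under the limit at 0.94 and 0.96. Of 13 NRF2 targets 4 were higher and 0 lower, with a median of 0.69 (adjusted p = 1.59e-09), namely AKR1B10 (1.43 ± 0.05), AKR1C3 (1.40 ± 0.16), AKR1C2 (1.33 ± 0.14) and TALDO1 (1.003 ± 0.10). Without the Hep3B arrays AKR1C3 was at 0.98 and AKR1C2 at 0.92, and TALDO1 lay at the limit, with 0.99 without replicate 5 and 0.84 after quantile normalization. Against the control, the median of the NRF2 targets was larger in SNU-475 (1.07) than in SNU-368 (0.92), and that of the cholangiocyte markers was larger in SNU-182 (0.64) than in SNU-368 (0.32). CAV1, of membrane caveolae, was higher by 1.85 ± 0.08 and NEFL, a neurofilament, by 1.84 ± 0.08. The lowest were PEG10 (-2.73 ± 0.10), RBP4 (-2.27 ± 0.17) and the uncertain PTK2 probe (-2.07 ± 0.18), and 10 of 32 plasma protein genes were lower and 0 higher (adjusted p = 7.60e-10). The epithelial junction list had a median of -0.04 and 1 of 18 higher against a camera direction of up (adjusted p = 0.0446), with an adjusted p = 0.212 with an estimated correlation. In all 142 genes were called, 102 higher and 40 lower.

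SNU-387 was high in FDCSP and LUM and low in keratins. FDCSP, a secreted peptide of follicular dendritic cells, was higher by 5.08 ± 0.20 (SE, n = 4 arrays, limma adjusted p = 8.41e-20), LUM, a collagen-binding proteoglycan, by 3.77 ± 0.09, and TMEM176A by 3.66 ± 0.13. Collagens and matrix genes had 5 of 21 higher (camera adjusted p = 0.0108), including TIMP3, a protease inhibitor (2.70 ± 0.09); the adjusted p = 0.0716 with an estimated correlation. Mesenchymal genes had 3 of 21 higher and 1 lower (adjusted p = 0.0105), with THY1 (1.56 ± 0.13), CDH2, N-cadherin (1.23 ± 0.10), and SPARC (1.22 ± 0.07) higher; the adjusted p = 0.0914 with an estimated correlation. Of 18 epithelial junction genes 5 were lower and 0 higher (adjusted p = 2.83e-06), among them the keratins KRT8 (-1.66 ± 0.04) and KRT18 (-1.51 ± 0.04). Cholangiocyte markers had 3 of 8 lower (adjusted p = 0.00269) and oncofetal markers 3 of 9 (adjusted p = 0.000487). The cytokine IL1B was higher by 2.22 ± 0.12. The lowest were TM4SF1 (-2.67 ± 0.06), PEG10 (-2.52 ± 0.10) and RSPRY1 (-2.37 ± 0.06), and 19 of 32 plasma protein genes were lower and 0 higher (adjusted p = 6.60e-12). In all 208 genes were called, 97 higher and 111 lower, and 88 and 55 after quantile normalization.

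SNU-449 had high vimentin and caveolin and low plasma protein transcripts. ARHGDIB, an inhibitor of Rho signalling, was higher by 2.59 ± 0.10 (SE, n = 4 arrays, limma adjusted p = 8.72e-20), CAV1 by 2.33 ± 0.08, PSG3, of a placental family with close paralogs, by 2.10 ± 0.13, and VIM by 1.81 ± 0.05. Mesenchymal genes had 4 of 21 higher and 1 lower (camera adjusted p = 0.0192), among them TAGLN, an actin-binding protein (1.51 ± 0.12), and MSN (1.43 ± 0.06); the adjusted p = 0.119 with an estimated correlation. COL1A2, a chain of type I collagen, was higher by 1.97 ± 0.08, and all 3 metallothioneins were higher, led by MT1E (1.74 ± 0.08), although without PLC/PRF/5 MT2A and MT1X stood at 0.97 and 0.99. The lowest were AGT (-2.77 ± 0.15), APOA2 (-2.50 ± 0.22) and E2F6, a transcriptional repressor (-2.21 ± 0.07), and APOA2 had 1 array far below the other 3. The SD of APOA2 over the SNU-449 arrays was 1.14, a spread that its pooled SE does not show. Of 32 plasma protein genes 15 were lower and 0 higher (adjusted p = 2.28e-15). The epithelial junction list moved down with a median of -0.35 (adjusted p = 5.24e-05) and the fatty acid oxidation list with a median of -0.30 (adjusted p = 0.000127), with 0 members past the threshold in either. In all 115 genes were called, 63 higher and 52 lower.

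SNU-475 had high collagen and SPANX transcripts. SPANXE (3.74 ± 0.13, SE, n = 4 arrays, limma adjusted p = 3.96e-20) and SPANXA1 (2.68 ± 0.12), sperm proteins with near-identical paralogs, and COL3A1, a chain of type III collagen (2.96 ± 0.12), were highest. Mesenchymal genes had 4 of 21 higher and 0 lower, with a median of 0.42 (camera adjusted p = 8.96e-10), including TAGLN (1.57 ± 0.12) and VIM (1.17 ± 0.05), which was at 0.996 without HepG2. Collagens and matrix genes had 3 of 21 higher (adjusted p = 8.94e-05), with COL5A1 at 1.15 ± 0.06 and COL1A1 at 1.12 ± 0.08, and stellate cell and fibroblast markers 2 of 9 (adjusted p = 9.19e-07). NRF2 targets had 2 of 13 higher (adjusted p = 4.08e-05), NQO1, a quinone reductase (1.40 ± 0.06), and AKR1B10 (1.17 ± 0.05). Cancer-testis antigens had 2 of 6 higher (adjusted p = 0.0369), with an adjusted p = 0.0636 with an estimated correlation, and the list missed the threshold without replicate 8 (adjusted p = 0.0824). CRYAB, a small heat shock protein, was higher by 2.18 ± 0.13. Ribosomal proteins moved down with a median of -0.27 (adjusted p = 7.60e-10) and 0 of 45 members past the threshold. The lowest were APOA2 (-1.92 ± 0.22), RBP4 (-1.74 ± 0.17) and the uncertain PTK2 probe (-1.73 ± 0.18), and 9 of 32 plasma protein genes were lower and 0 higher (adjusted p = 8.91e-09). In all 107 genes were called, 54 higher and 53 lower, and 163 after quantile normalization.

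**Figure D3:**
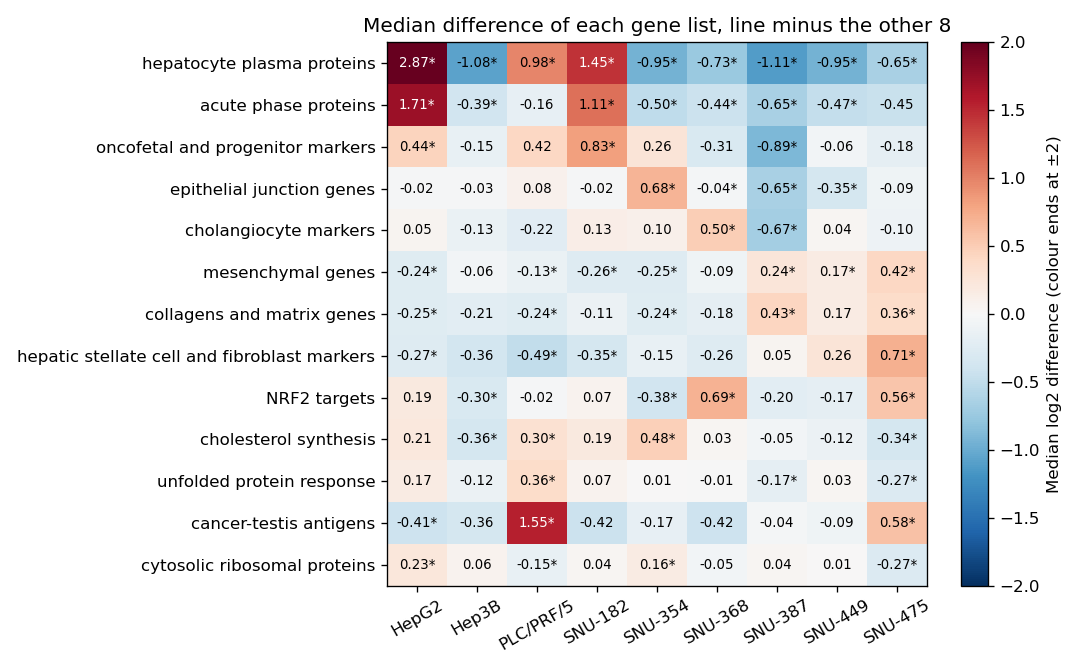
Median log2 difference of the members of 13 gene lists in each cell line against the other 8 lines, as numbers and as colour from blue (lower) to red (higher), with the colour ending at 2 in either direction. A star marks a camera adjusted p under 0.05 with the preset correlation, and plasma proteins carry a star in all 9 lines.

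CDH1, E-cadherin, passed in no line against the other 8, with log2 differences from -0.64 ± 0.28 in SNU-182 to 0.60 ± 0.28 in SNU-354. VIM was at 1.03 ± 0.05 in Hep3B and -1.18 ± 0.05 in PLC/PRF/5, and these became 0.86 without HepG2 and -0.97 without SNU-449. ALB was at -1.29 ± 0.08 in SNU-387, -1.02 ± 0.08 in SNU-354 and -1.01 ± 0.08 in SNU-449, and without HepG2 these became -0.85, -0.58 and -0.57. Lists of hepatocyte transcription factors, Wnt/beta-catenin liver targets, interferon response, lymphoid cell markers and neural and neuroendocrine markers were called in 0 of the 10 comparisons by camera.

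The comparison that the titles name is each line with the universal control. HepG2 held plasma protein transcripts above the control, with a median of 3.16 and 26 of 32 genes higher, followed by SNU-182 (2.26, 22 genes) and PLC/PRF/5 (1.27, 18 genes). The Hep3B median was -0.10, and those of the other 5 lines ran from -0.19 to 0.06. Of the 32 genes, 1 was called lower than the control in Hep3B and 0 in SNU-354, SNU-368, SNU-387, SNU-449 and SNU-475. By the limma moderated test on 4 arrays per line, 439 genes were called in HepG2 (307 higher, 132 lower), 213 in Hep3B (74 and 139), 389 in PLC/PRF/5 (279 and 110) and 330 in SNU-182 (228 and 102). The numbers were 135 in SNU-354 (87 and 48), 272 in SNU-368 (180 and 92), 313 in SNU-387 (155 and 158), 130 in SNU-449 (91 and 39) and 151 in SNU-475 (95 and 56). After quantile normalization the Hep3B balance turned to 176 higher and 91 lower, and SNU-449 had 218 called genes. Without dye exchange these ratios also hold any dye effect of a probe.

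Across the 9 lines together, ALDH1A1, AKR1C1 and ALDH2 stood above the control and BASP1, LDHB and CTAG2 below it. ALDH1A1, a retinaldehyde dehydrogenase, had a mean log2 ratio of 2.11 ± 0.27 (SE, n = 9 lines, limma adjusted p = 0.000873), AKR1C1 1.70 ± 0.26 and ALDH2, the mitochondrial acetaldehyde dehydrogenase, 1.48 ± 0.19. The single probe annotated to PM20D2, a name that is uncertain, was highest at 3.09 ± 0.48, and UBE2L6, an ISG15-conjugating enzyme, was at 1.89 ± 0.18 and FABP5, a fatty acid carrier, at 1.77 ± 0.25. CLIP2 (1.40 ± 0.18) and APOC1, a lipoprotein component (2.08 ± 0.48), also passed, the latter with an adjusted p = 0.0584 without the Hep3B and SNU-182 arrays. CNTN2 (1.45 ± 0.46) and AIFM3 (1.36 ± 0.41) passed too, but missed without HepG2 (adjusted p = 0.0857 and 0.0721) and likewise without PLC/PRF/5, SNU-182 or SNU-368. Below the control were BASP1, a membrane protein of growth cones (-2.25 ± 0.28), LDHB (-2.15 ± 0.46), the testis antigens CTAG2 (-2.07 ± 0.25) and LY6K (-1.80 ± 0.11), and PRSS21, a testis protease (-1.82 ± 0.12). FOLR1, a folate receptor (-1.89 ± 0.25), HPD (-1.87 ± 0.33), the kinase FYN (-1.69 ± 0.15), TFAP2A (-1.51 ± 0.18) and CAPG, an actin capping protein (-1.46 ± 0.26), were lower as well. Of 13 NRF2 targets 4 were higher and 0 lower, and also 4 adjusted over the list alone, namely AKR1C2 (2.94 ± 0.51), AKR1C3 (2.91 ± 0.45), AKR1C1 and NQO1 (1.03 ± 0.24), the last at 0.88 without SNU-475 or SNU-387. Of 8 cholangiocyte markers 2 were higher, SPP1 (2.43 ± 0.49) and ANXA4 (1.18 ± 0.28), and 2 adjusted over the list alone. ANXA4 had an adjusted p = 0.0653 without the Hep3B and SNU-182 arrays. In all 81 genes were called, 35 higher and 46 lower, of which 17 and 34 had the same sign in every line. Of the 35 lists, the cancer-testis antigens were the only one whose count changed when adjusted over the list alone, from 1 to 2 of 6 lower. No list test was run for this comparison.

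The names of the lines carry 1 grouping, the 6 SNU lines against HepG2, Hep3B and PLC/PRF/5. It takes the Hep3B and SNU-182 labels as given, and an exchange of these labels could not be settled. No gene passed: limma called 0 genes with the line as the replicate, with 465 at an unadjusted p under 0.05. The smallest p in each direction belonged to YWHAE, a 14-3-3 adaptor protein (0.67 ± 0.11, SE, n = 6 and 3 lines, adjusted p = 0.853), and PDIA2, a disulfide isomerase (-0.74 ± 0.11, adjusted p = 0.5001). CCT5, a chaperonin subunit, was at 0.91 ± 0.22 and GPX4, a lipid peroxidase, at -0.83 ± 0.17. Plasma proteins had a median of -1.09 with 0 of 32 past the threshold (camera adjusted p = 3.95e-09), with an adjusted p = 0.332 with an estimated correlation. Stellate cell and fibroblast markers had a median of 0.55 (adjusted p = 0.0104), with an adjusted p = 0.311 with an estimated correlation. Lists of xenobiotic metabolism, collagens and the unfolded protein response were also called and also lost, with an adjusted p = 0.193, 0.419 and 0.413 with an estimated correlation. With the line as a random block over all arrays, 25 genes were called, and without the Hep3B and SNU-182 arrays, an alternative added after the data had been seen, 41 were. The simulated test at this size recovered 89% of changes of 1.5 on the log2 scale. That share is an average over genes drawn at random. It does not give the recovery for genes that vary strongly between lines, such as those of plasma proteins.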

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

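The test for HepG2 RNA on the SNU-182 arrays was chosen only after the hepatocyte values had been seen, as were its limit, the condition that leaves the RB1 test open, and the readings of the tests of the SNU-475 spread and missing values as void.

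The 9 lines differed from each other in their ratios to the control, with 1924 genes by the F-test. When the arrays were regrouped at random, 1 of 100 splits, the real one, gave as many genes, and the highest of the others gave 99, so a random grouping of the arrays can be excluded for that count. This shows that arrays of a line resemble each other and says nothing about other cultures. The same held for each line against the other 8, with 1 of 100 splits, the real one included, as large. The real counts and the highest of the other splits were 277 and 6 for HepG2, 218 and 26 for Hep3B, 252 and 73 for PLC/PRF/5, 150 and 67 for SNU-182, and 143 and 11 for SNU-354. They were 142 and 100 for SNU-368, 208 and 196 for SNU-387, 115 and 8 for SNU-449, and 107 and 3 for SNU-475. For the 6 SNU lines against the 3 others, 84 of 84 splits gave as many genes as the real 0, which a count of 0 fixes in advance, so these splits say nothing about chance. The highest other split set HepG2, PLC/PRF/5 and SNU-182 apart and called 54 genes. It is the highest of 84 splits and holds the 3 lines already seen to be high in plasma proteins, so it is no independent test of that pattern. It is also the grouping by name that exchanged Hep3B and SNU-182 labels would give. Such an exchange could not be settled, so the count of 0 holds only for the labels as given.

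Among 148 groups of values looked at, some held the 4 arrays of a line and others held line means. In 6 of them 1 value lay far from the rest. All 6 were groups of 4 arrays, and chance gives about 1 in 20 such groups. SNU-449 replicate 8 lacked 2 values where the others lacked 0. PLC/PRF/5 replicate 8 had a mean Pearson correlation with its own line of 0.819, against 0.858 to 0.864 for the others. SNU-182 replicate 8 had a median log2 ratio of the plasma protein genes of 1.79, against 2.21 to 2.27. MAGEA2 in PLC/PRF/5 replicate 5 was at 2.03, against 2.21 to 2.22. S100A1 in PLC/PRF/5 replicate 8 was at -3.59, against -4.08 to -4.02. APOA2 in SNU-449 replicate 7 was at -2.21, against -0.12 to 0.17.

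Plasma protein transcripts stood near the control level in the Hep3B arrays and well above it in the SNU-182 arrays. The array centring and scaling applied here is argued against, since the smallest median difference, SNU-182 minus Hep3B, over the scaling alternatives was 2.04 on the log2 scale. That value came from quantile normalization, and the difference without centring was 2.36. Deposited array medians were already near 0, so centring could hardly move it. The unknown normalization before deposit was not tested. HepG2 RNA as the source of these transcripts on the SNU-182 arrays stays open: 6 of 53 members of 3 liver lists were higher there than in HepG2, of which 4 were above every other line and 1, HAMP (1.15 ± 0.41), was at least 2-fold higher, and so few members decide nothing for the rest. An exchange of the Hep3B and SNU-182 labels could not be settled. RB1, whose product Hep3B is known to lack, was higher in SNU-182 by 0.33 ± 0.09, the direction predicted without an exchange. But no line had a low RB1 mean (-0.14 in Hep3B to 0.22 in SNU-368) and the Hep3B probes disagreed at -0.52 and 0.25. The test was therefore taken as void and counts for neither side. Likeness to HepG2, with 83 called genes against SNU-182 and 527 against Hep3B, cannot settle it without a separate reference for either line. A difference between the lines themselves, which the design names, also stays open and was not tested.

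HepG2 had 277 called genes and SNU-475 had 107, a ratio of 2.59. The ratio was 2.57 with the 8756 of 8799 genes complete on all arrays, a filter too light to move it, and fewer missing values on the SNU-475 arrays (0 to 9, against 55 to 69 in HepG2) give no reason for a lower count, so this test was void. A narrower spread of the log ratios on the SNU-475 arrays cannot be told apart from a difference of the lines: the ratio was 3.29 after scaling to 1 median absolute deviation, but that deviation was already wider on the SNU-475 arrays (0.332 to 0.334) than on the HepG2 arrays (0.286 to 0.287), so this test was void too. Quantile normalization, which makes all distributions alike and so also removes true differences in spread, gave 1.04 (170 and 163 genes). The deviation also went in steps by sets of lines, so a scaling applied by set cannot be told apart from the lines either. A difference between the lines themselves stays open and was not tested.

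The NRF2 targets were higher in SNU-368 than in the mean of the other 8 lines, as they also were in SNU-475, and in SNU-368 2 of the 4 called members were AKR1C paralogs. Signal shared between these paralogs as the whole cause is argued against, since without the AKR1C members the median difference was 0.52, with quartiles of 0.18 and 0.72 and 10 of 10 members above 0. Other technical explanations were not tested, and a difference between the lines themselves stays open.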

How the results depend on the processing

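The fit without the Hep3B and SNU-182 arrays was chosen only after the results had been seen, and all other alternatives were planned. Intensities were not analysed here, so signal over background sets no filter and weak probes stand beside strong ones. Of 398 named gene results past the threshold, 52 stayed past it in every alternative; over their 10819 alternatives 10069 kept direction and side, 749 kept the direction but no longer passed and 1 reversed. Over the list results 1231 kept direction and side, 124 no longer passed and 0 reversed. The median of all line means stayed between -0.01 and 0.00 under every scaling.

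With no fold limit, which enlarges each count by construction, the F-test passed 7416 genes, the mean of the 9 lines 2153 and the median pair 3613. In the order HepG2, Hep3B, PLC/PRF/5, SNU-182, SNU-354, SNU-368, SNU-387, SNU-449, SNU-475, the counts against the other 8 were then 3797, 3914, 3524, 3258, 3440, 3433, 4124, 3771 and 3789, and against the control 4328, 4087, 4621, 4682, 4297, 4885, 4928, 4204 and 3776. Counted per probe, which tests more items, the F-test passed 6667, the mean of the 9 lines 273 and the median pair 1191; against the other 8 the counts were 862, 783, 793, 477, 527, 555, 784, 402 and 374, and against the control 1245, 890, 1349, 1015, 558, 1031, 1103, 501 and 681. With the spread between lines as the error they were 0, 2, 22, 1, 11, 8, 30, 9 and 0, since that error holds the differences between the other lines; this was run with the mean of the line, and the planned form with its 4 arrays was not run.

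Quantile normalization gave 170 genes in HepG2 and 163 in SNU-475 against the other 8, and 218 in SNU-449 against the control. It moved the share of higher genes from 26.1% to 53.8% in Hep3B, 74.4% to 63.5% in HepG2, 46.6% to 61.5% in SNU-387 and 50.5% to 64.4% in SNU-475, and against the control from 34.7% to 65.9% in Hep3B and 49.5% to 61.5% in SNU-387; the cause was not tested. The SNU comparison called 25 genes with the line as a random block, which counts arrays as replicates, and 41 without the Hep3B and SNU-182 arrays, whose cause was not tested. Of the list tests, 54 were called with an estimated correlation, 76 on ranks and 220 by fry, which tests a different hypothesis. Without 1 replicate the F-test gave 1942 to 1997 genes, the mean of the 9 lines 77 to 83 and the list tests 92 to 103.

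Results that reversed had not passed the threshold, except COL6A3 in SNU-449, which was at 1.14 from 2 probes and at -0.18 with only rows complete on all 36 arrays, a filter that leaves 1 of the 2 probes. ALB in the SNU comparison ran from -2.06 to 0.19 over the fits without 1 line, the latter without HepG2, and CTAG2 in HepG2 was at 0.020 after quantile normalization. CDH1, with differences near 0, reversed in some fits without 1 replicate or line, over which it ran from -0.25 to 0.0068 in the SNU comparison, -0.035 to 0.20 in HepG2, -0.039 to 0.30 in PLC/PRF/5, -0.91 to 0.065 in SNU-182, -0.051 to 0.45 in SNU-387 and -0.27 to 0.076 in SNU-449. In HepG2 it was also at -0.030 without the Hep3B and SNU-182 arrays.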

Other observations

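No test in this part was chosen only after a result was seen; the list tests were planned, and the single genes were picked by the fixed rule.

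Single inflammatory and heat shock genes differed between lines. The chemokine CCL20 was higher in PLC/PRF/5 (3.47 ± 0.11, SE, n = 4 arrays) and SNU-182 (1.82 ± 0.11) and lower in Hep3B (-1.68 ± 0.11), SNU-387 (-1.21 ± 0.11), SNU-475 (-1.22 ± 0.11) and SNU-449 (-1.11 ± 0.11), and without PLC/PRF/5 the last 3 were at -0.79, -0.80 and -0.69. The chemokines CXCL5 (1.34 ± 0.06) and CXCL3 (1.55 ± 0.16) were also higher in PLC/PRF/5, and the interleukin IL1A was higher in SNU-387 (1.54 ± 0.12). Of the small heat shock proteins, CRYAB was higher in SNU-475 (2.18 ± 0.13) and SNU-387 (1.60 ± 0.13), and HSPB1 was lower in HepG2 (-2.41 ± 0.07) and SNU-182 (-1.56 ± 0.07). The mitochondrial chaperone HSPD1 was higher in SNU-182 (1.497 ± 0.06) and lower in SNU-475 (-1.27 ± 0.06).

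As a list, xenobiotic and bile acid metabolism moved up in HepG2, with 3 of 17 members higher (camera adjusted p = 0.00193), and down in SNU-354, with 0 of 17 past the threshold (adjusted p = 0.000247). It was also called down in SNU-449 (adjusted p = 0.0237) and SNU-387 (adjusted p = 0.0440), but with an adjusted p = 0.131 and 0.174 with an estimated correlation. Of single enzymes, CYP1A1, which oxidises aromatic hydrocarbons, was higher in PLC/PRF/5 (2.63 ± 0.10), and CYP3A4, a drug-oxidising enzyme, in Hep3B (1.49 ± 0.04). CPS1, the entry enzyme of the urea cycle, was higher in PLC/PRF/5 (2.36 ± 0.10). PLIN2 was higher in SNU-449 (1.88 ± 0.09) and lower in SNU-354 (-1.38 ± 0.09). BAAT, which conjugates bile acids, was higher in SNU-368 (1.48 ± 0.06).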
